A study of Homo sapiens with 7 samples.

How the data were processed

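Transposon insertions were mapped in HCT116, an established human colon carcinoma cell line, after expression of the piggyBac (PB) transposase in 2 forms. The wild-type transposase (WT_PB) was used in 3 libraries and the transposase fused to the transcription factor SP1 (SP1_PB) in 2 libraries. The series also holds 1 list of SP1 ChIP-seq peaks and 1 polyA RNA-seq library of HCT116 cells. Per the labels' protocols, cells carrying an integrated transposon were selected with the drug G418, their genomic DNA was cut with 3 restriction enzymes in separate aliquots, circularised and amplified by inverse PCR, and the pooled products were sequenced on an Illumina GAII instrument. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures, so p-values from tests across libraries measure only the spread between these samples, which may be technical. Fisher's exact p-values on pooled insertions do not measure that spread.

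The insertion files hold, per the deposited readme, a chromosome, a position and a count of reads for each insertion, from reads aligned to hg18 with bowtie (version 0.12.7 per the submitters' processing notes). These counts were deposited without normalization, no filter on reads is stated, and the strand is not given. Chromosomes are written as numbers; 23 and 24 were read as X and Y because the last insertion under each code lay close to the last peak of that chromosome, at 154873461 against 154764560 and at 57765592 against 57766474. Some positions were listed in several lines. What separates such lines is not stated, so lines at the same position were merged and their reads summed, and each distinct position counted as 1 insertion whatever its reads. The plan had assumed that the strand would be given.

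The peak list holds the output of the peak caller MACS, per the deposited readme, with a score per peak that is the authors' own. The lowest score was 200.01; the scale of the score, the MACS version, its threshold and its control are not given in the sources used here. The peaks came from 1 sample, and the score was used only to rank peaks within this list. Gene expression was deposited as RPKM per RefSeq gene, per the deposited readme from reads aligned to hg18 with TopHat and quantified with Cufflinks (version 1.1.0 per the submitters' processing notes). The RNA library has no replicate and its depth is not given in the sources used here, so no test or interval was computed for it. Genes that most cells express, such as YWHAZ, were among those at 0, so a value of 0 is described only as listed at 0.

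The distance of each insertion to the edge of the nearest peak was computed, with 0 inside a peak. The main measure was the share of a library's insertions within 1 kb of a peak. Pooled shares of the groups were compared with Fisher's exact test (two-sided), which covers counting error only and treats insertions as independent. The 5 library values were compared with an exact permutation test (two-sided); with 10 splits its smallest possible p is 0.1, so it cannot pass 0.05. A difference was called only when, in addition, every SP1_PB library lay on the same side of every WT_PB library. Shares of single libraries have 95% Wilson intervals, and ratios of pooled shares 95% log-normal intervals. PCR reads without molecular identifiers are not independent molecules, and all intervals and floors cover counting error only. The background was the mean of 100 draws of random positions, matched to each library's insertions per chromosome and not restricted to TTAA sites. Peaks were divided into 4 groups of equal size by score. For the share of peaks with an insertion, each library was reduced to 14467 insertions, the size of the smallest, in 20 draws.

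Insertions were counted in 50 kb windows fixed from coordinate 1 of each chromosome. Windows with at least 5 insertions over the 5 libraries were tested with Fisher's exact test on pooled insertions, with Benjamini-Hochberg adjustment. A window was called at an adjusted p under 0.05 when both SP1_PB libraries deviated in the same direction from the pooled WT_PB share. The same test was run between libraries of one group. Chromosome shares were tested in the same way and called when no SP1_PB library lay within the range of the WT_PB libraries. Where one group had no insertion in a window, the ratio was computed against a floor of 3 insertions over that group and is a bound. The window test was tested on simulated counts drawn from the WT_PB densities in 49628 windows. It called 11 of 100 windows raised 5-fold, 18 of 50 raised 10-fold and 0 of 50 lowered to 0.1-fold. Of the 50 lowered windows 21 held enough insertions to be tested. Most changes of these sizes in thinly filled windows thus go uncalled. There were 0 false calls, but the counts were Poisson draws without clustered positions or extra spread between libraries. They cannot show how often the real counts give false calls. The edgeR quasi-likelihood test, an alternative, called 13, 20 and 0 of windows simulated in the same way.

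Windows, peaks, genes and lists named in the text follow a rule written before the data were examined, as were the main tests, the gene lists and most of the alternatives. That plan did not hold the comparison by ranges of distance or the share of peaks with an insertion. Nor did it hold the comparison of peak presence between called and other windows, or the relation of chromosome ratios to peaks per Mb. Named were the 15 higher and 10 lower windows with the smallest p, the 5 peaks with the highest score, every called chromosome, the 5 genes with the highest RPKM, the SP and KLF family members listed above 0, and in each other list up to 4 members with the highest and up to 2 with the lowest value, from which examples are printed. The same rule named genes by their starts, and comparisons of insertions with gene starts, gene bodies and expression classes had been planned for the case that hg18 gene coordinates were at hand. Gene coordinates of that build were not used here, so these comparisons were not made and windows are given by hg18 coordinates without genes. Symbols were used as the expression file gives them. The median RPKM of each list was set against 10000 random lists of the same size.

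Alternatives covered the distance to the peak, stricter peak sets, reads per insertion, repeated positions, window size and placement, the minimum per window, the test, and each library left out in turn. Further alternatives were added after the data had been seen, among them merging positions within 3 bp of each other. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16; random draws used the seed 20120101.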

Results

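The piggyBac transposase inserts a transposon at TTAA sites, and calling cards are such insertions left in the genome where a DNA-binding protein fused to the transposase has been. The libraries compared here map insertions made in HCT116 cells by the wild-type transposase (WT_PB, 3 libraries) and by the transposase fused to SP1 (SP1_PB, 2 libraries). SP1 is a zinc finger transcription factor that binds GC-rich promoter sequences. The WT_PB libraries held 58850, 67423 and 57419 distinct positions from 1239637, 2439456 and 1030567 reads, with a median of 3, 4 and 3 reads per position. The SP1_PB libraries were smaller in positions, with 18856 and 14467 from 904125 and 1004964 reads, and deeper per position, with medians of 6 and 13 reads. Merging positions within 3 bp of each other would remove 4.07%, 5.24% and 5.36% of the positions of the WT_PB libraries and 11.9% and 15.8% of those of the SP1_PB libraries. TTAA sites cannot start that close together, so such neighbours may be the same site counted more than once. The main counts, ratios and p-values keep them apart and may be inflated, more so for SP1_PB. The SP1 ChIP-seq sample gave 27015 peaks with a median width of 825 bp that covered 26.1 Mb of hg18.

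Insertions of the SP1 fusion lay near SP1 ChIP-seq peaks far more often than those of the wild-type transposase, the comparison for which the wild-type libraries serve as background. Within 1 kb of a peak lay 41.5% ± 0.306 of SP1_PB insertions (SD, n = 2 libraries) and 7.95% ± 0.232 of WT_PB insertions (SD, n = 3). The SP1_PB libraries stood at 41.3% (95% Wilson interval 40.6 to 42.0) and 41.8% (41.0 to 42.6), and the WT_PB libraries between 7.69% and 8.15%. Inside peaks the gap was wider, with 22.2% ± 0.357 against 1.95% ± 0.121. Both transposases exceeded random positions: the SP1_PB share was 12.2 ± 0.0246 times and the WT_PB share 3.02 ± 0.0748 times that of random positions, which were not restricted to TTAA sites.

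The pooled ratio of the shares within 1 kb was 5.23 (95% interval 5.13 to 5.34), it ranged from 5.07 to 5.43 over the 6 pairs of an SP1_PB with a WT_PB library, and Fisher's exact test gave a p below 1e-300. The exact permutation test over the 5 libraries gave p = 0.1, the smallest that its 10 splits allow. Inside peaks the pooled ratio was 11.3 (10.9 to 11.8). Within 10 kb it was 2.83, more than 1.5 times below the value at 1 kb.

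**Figure D1:**
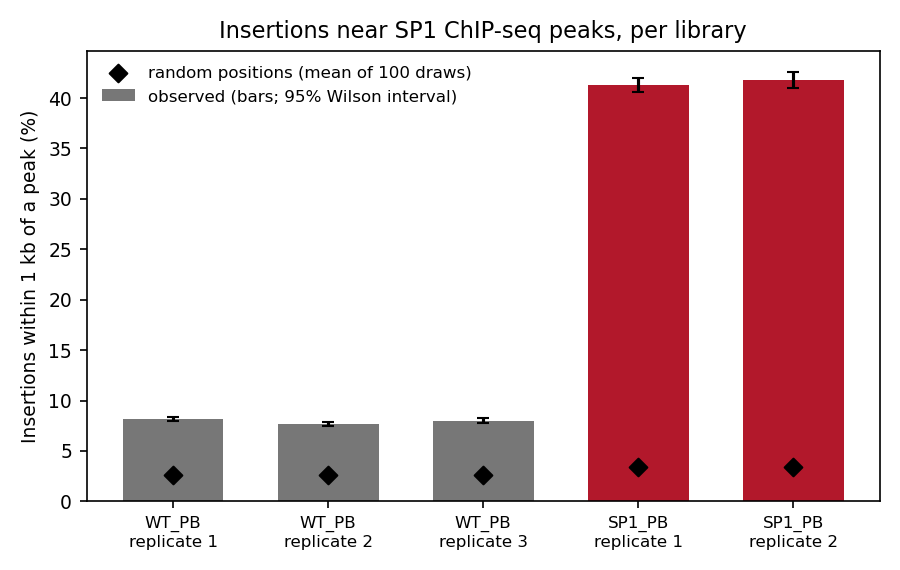
Bars give the percentage of each library's insertions within 1 kb of an SP1 ChIP-seq peak with 95% Wilson intervals, and diamonds the mean of 100 draws of random positions matched by chromosome. The 2 SP1_PB libraries stood at 41.3% and 41.8% and the 3 WT_PB libraries between 7.69% and 8.15%.

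The excess of SP1_PB insertions fell with distance from the peak. The ratio of SP1_PB to WT_PB shares was 11.3 inside peaks, 3.65 at 1 to 500 bp, 2.34 from there to 1 kb and 1.92 at 1 to 2 kb. Between 5 and 10 kb the shares were close, at 6.48% ± 0.113 against 6.05% ± 0.211 with a ratio of 1.07 (1.02 to 1.12, adjusted Fisher's exact p = 2.66e-03). Beyond 10 kb the SP1_PB shares were lower than the WT_PB shares. The shares of a library sum to a whole, so an excess near peaks by itself lowers the shares farther away. Numbers of insertions per cell were not measured. More than 100 kb from any peak lay 13.1% ± 0.670 of SP1_PB insertions and 38.2% ± 1.28 of WT_PB insertions, a ratio of 0.345 (0.335 to 0.355). In each of the 10 distance ranges both SP1_PB libraries lay outside the range of the WT_PB libraries.

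**Figure D2:**
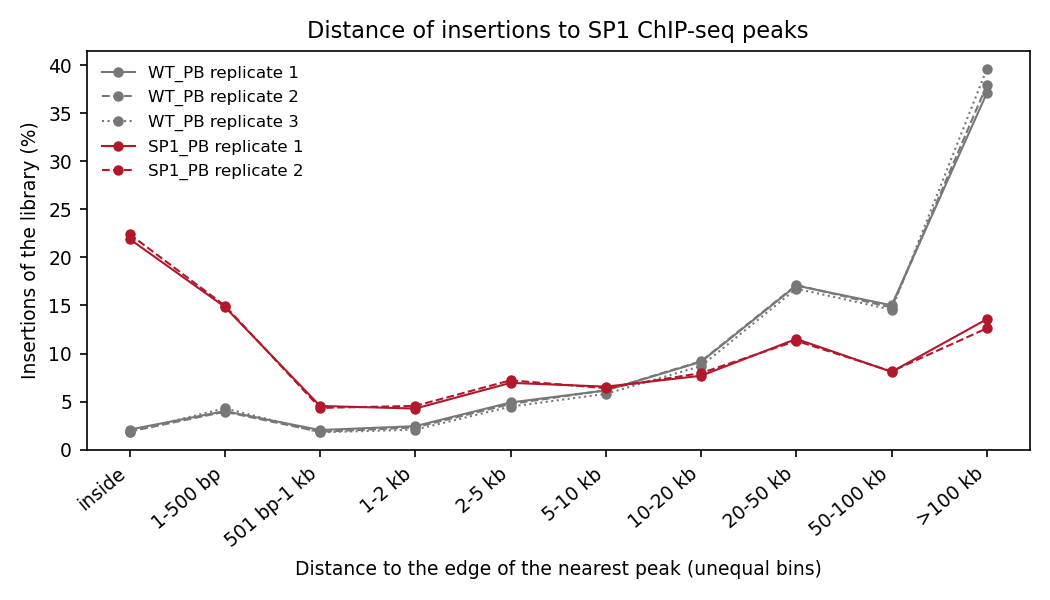
Lines join the percentage of each library's insertions in 10 ranges of distance to the edge of the nearest SP1 ChIP-seq peak, with SP1_PB in red and WT_PB in grey. The libraries of a group nearly overlay, and the groups cross between 5 and 20 kb.

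The excess of SP1_PB insertions was larger at peaks with high scores, which were also wider, than at peaks with low scores. Each group of peaks was taken with the insertions near no peak, and the shares at the group were compared. The ratio of SP1_PB to WT_PB shares was 6.28 (5.91 to 6.68) at the fourth of peaks with the lowest scores, from 200.01 to 273.3, then 6.83 and 6.94, and 7.63 (7.39 to 7.88) at the fourth with the highest, from 597.12 to 3219.84. Over pairs of libraries the ratio ranged from 5.71 to 6.77 in the lowest and from 7.12 to 8.19 in the highest group. At equal numbers of insertions, 15.0% ± 0.605 of all peaks had an SP1_PB insertion within 1 kb and 4.11% ± 0.103 a WT_PB insertion. In the highest group these shares were 27.0% ± 0.929 and 6.42% ± 0.409. Most peaks carried none: 20646 peaks (76.4%) had no SP1_PB insertion within 1 kb in either library, and 796 had 5 or more. These numbers depend on depth. In SP1_PB replicate 1 the share of peaks with an insertion was 15.4% at 14467 positions and 18.1% at all 18856. The median width rose from 604 bp in the group with the lowest scores to 1152 bp in that with the highest. With peaks grouped by width instead, the ratio rose from 5.75 to 8.93, and score and width were not separated.

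Of insertions near the highest or lowest group, those of SP1_PB were more often at the highest, with an odds ratio of 1.48 (1.38 to 1.59, Fisher's exact p = 3.99e-27), a test added after the data had been seen. Counts at the 5 peaks with the highest scores varied. The peak at chromosome 8, 8122156 to 8124096, had 16 SP1_PB and 8 WT_PB insertions within 1 kb. The peak at chromosome 15, 100318622 to 100320180, had 3 and 4. The strongest peak of all, at chromosome 17, 74347444 to 74349373, had 1 SP1_PB insertion and no WT_PB insertion, as did the peak at chromosome 8, 102161479 to 102162716. The peak at chromosome 3, 198865187 to 198866767, had no SP1_PB and 1 WT_PB insertion. Single peaks were not tested.

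Regions with an excess of SP1_PB insertions were scattered over the genome and nearly always held an SP1 peak. Of 15678 windows of 50 kb tested, 1079 had more and 26 had fewer SP1_PB insertions than WT_PB insertions relative to the library totals. Of the higher windows 995 (92.2%) held a peak, against 42.8% of windows not called (Fisher's exact p = 1.40e-244), and of the lower windows 2 (7.69%, p = 1.85e-04). This comparison was not among the planned tests. A lower call needs many WT_PB insertions, and windows picked by that count alone also mostly lacked peaks. The comparison for lower windows therefore cannot tell a lower SP1_PB share from a high WT_PB count. The higher windows held 27.9% of all SP1_PB and 2.80% of all WT_PB insertions, a gap that follows in part from calling them on these same counts. Chromosome 19 was the richest in them, with 155 of its 520 tested windows (29.8%).

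The test between libraries of one group called 0 windows in each of its 4 comparisons, although 516, 373 and 577 of 12733 windows in the WT_PB comparisons and 53 of 1757 in the SP1_PB comparison had an unadjusted p under 0.05. The counts depended on how insertions were counted. Without positions that occurred in more than 1 library 522 higher and 5 lower windows were called, 508 and 5 of them among those above. With positions within 3 bp merged 706 and 11 were called (703 and 11 among those above), and with 1 insertion per 1 kb cluster 228 and 0 (227 and 0). In windows of 1 Mb the balance turned, with 333 higher and 439 lower. With a single SP1_PB library the test called 482 higher windows for replicate 1 and 375 for replicate 2, and 1 lower window for each.

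Among the 15 higher windows with the smallest p, 9 lay on chromosome 19, 2 on chromosome 17 and 1 each on chromosomes 3, 6, 12 and 20. They were picked by p from the same counts, so their ratios and intervals tend to overstate the excess. The leading window, chromosome 19 from 45.80 to 45.85 Mb, held 6 peaks and 49 SP1_PB insertions, 26 and 23 per library, against 6 WT_PB insertions. Its ratio was 45.0 (19.3 to 105, adjusted Fisher's exact p = 2.22e-29), and 42 of the 49 lay within 1 kb of a peak. A neighbouring window, from 45.60 to 45.65 Mb, held 9 peaks, 37 SP1_PB and 14 WT_PB insertions, a ratio of 14.6 (7.88 to 26.9). Most positions of SP1_PB replicate 2 in both windows also occurred in SP1_PB replicate 1. The pooled counts, p-values and intervals take such positions as separate insertions. Both windows kept their call in all 12 alternatives run for them, among them that without positions in more than 1 library. On chromosome 12 from 55.75 to 55.80 Mb 36 SP1_PB insertions stood against 4 (ratio 49.6, 17.7 to 139), and on chromosome 17 from 73.60 to 73.65 Mb 31 against 2 (85.4, 20.5 to 357). On chromosome 3 from 38.00 to 38.05 Mb 23 SP1_PB insertions stood against 1, a ratio of 127 with an interval from 17.1 to 939. The window on chromosome 19 from 59.15 to 59.20 Mb held 19 SP1_PB insertions and no WT_PB insertion, at least 34.9-fold more against a floor of 3 WT_PB insertions over the group.

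All 15 windows held a peak, and 273 of their 386 SP1_PB insertions (70.7%) lay within 1 kb of one. In these peak-rich windows WT_PB insertions often did so too, so this share cannot be set against the WT_PB share of the whole genome. On chromosome 19 at 45.60 Mb 10 of 14 WT_PB and 24 of 37 SP1_PB insertions lay within 1 kb of a peak. In the leading window they were 2 of 6 and 42 of 49. The rest of the 15 lay on chromosome 19 at 53.80, 53.50, 12.70, 7.55, 10.80 and 18.15 Mb, on chromosome 20 at 60.85 Mb, on chromosome 17 at 39.60 Mb and on chromosome 6 at 149.90 Mb. Their ratios ran from 19.7 to 105. Not every such window followed its peaks: on chromosome 6 from 149.90 to 149.95 Mb 0 of 21 SP1_PB insertions, and on chromosome 19 from 7.55 to 7.60 Mb 1 of 20, lay within 1 kb of a peak. With 1 insertion per 1 kb cluster both of these windows were no longer called, nor were those on chromosome 17 at 73.60 Mb and on chromosome 19 at 10.80 Mb. Each of these windows kept a ratio above 1 with such clusters. With 0.5 insertions added to each group, these clusters lowered the ratio on chromosome 17 at 73.60 Mb from 69.5 to 9.07 and that of the leading window on chromosome 19 from 42.0 to 15.9. With positions within 3 bp merged, the window on chromosome 17 at 73.60 Mb fell from 31 to 14 SP1_PB insertions and its ratio from 85.4 to 42.5, and that on chromosome 19 at 10.80 Mb fell from 22 to 12 and from 24.3 to 14.6.

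**Figure D3:**
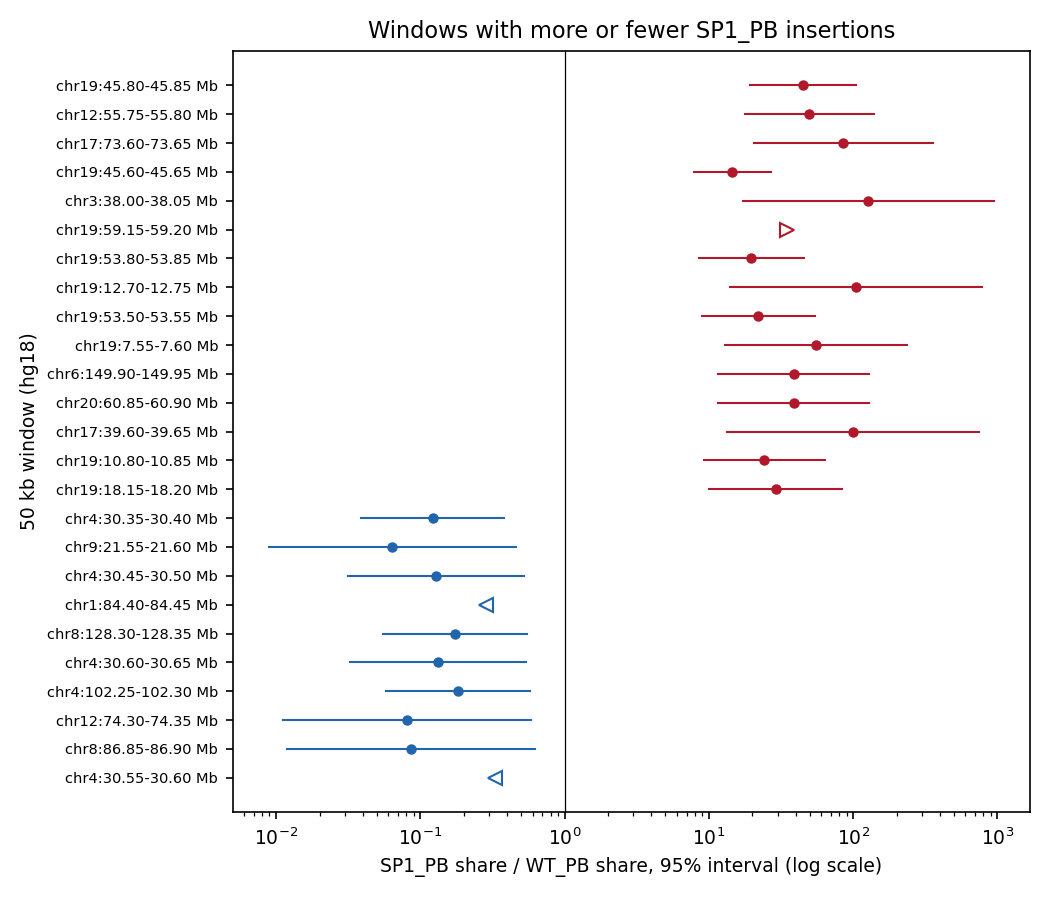
Points give the ratio of SP1_PB to WT_PB shares in the 25 named 50 kb windows on a log scale with 95% intervals, red for higher and blue for lower, and open triangles mark bounds where 1 group had no insertion. The 15 higher windows lie between 14.6 and 127 and the 10 lower windows at or below 0.331.

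**Figure D4:**
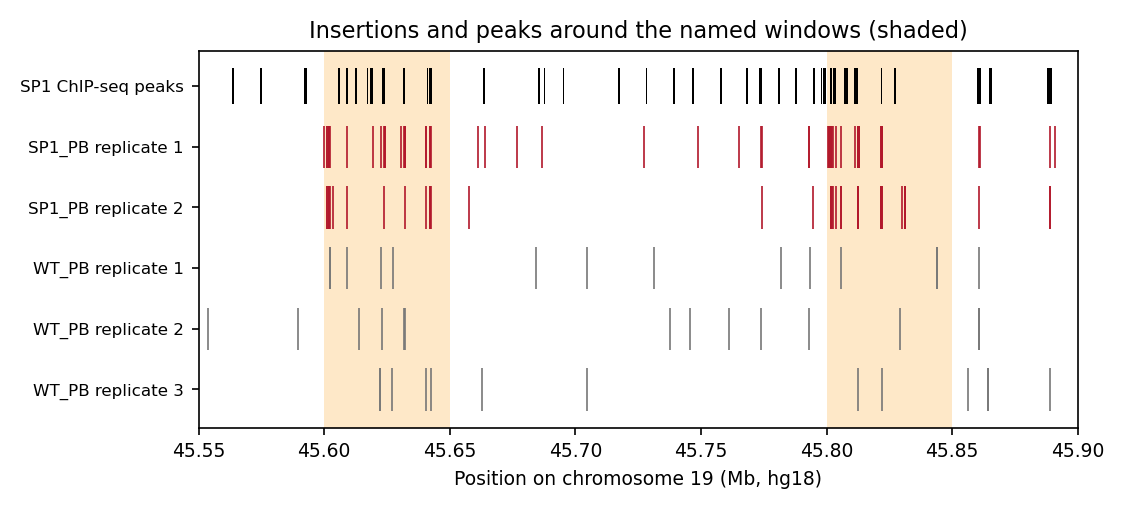
Vertical lines mark the insertions of each library and black bars the SP1 ChIP-seq peaks on chromosome 19 from 45.55 to 45.90 Mb (hg18), with the 2 named windows shaded. The SP1_PB libraries show 64 and 44 insertions on this stretch and the larger WT_PB libraries 14, 14 and 13.

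Windows of 50 kb called with a lower share of SP1_PB than of WT_PB insertions were mostly without peaks. Windows picked by their WT_PB count alone also mostly lacked peaks, as given under other observations. The number of lower windows is no measure of how common such regions are, since the test called 0 of 50 simulated windows lowered to 0.1-fold. Of the 10 lower windows with the smallest p, 5 lay on chromosome 4, 2 on chromosome 8 and 1 each on chromosomes 1, 9 and 12, and only that on chromosome 9 held a peak. Together they held 817 WT_PB and 16 SP1_PB insertions, and 2 of them held no SP1_PB insertion. A window with any insertion held 0.671 SP1_PB insertions on average, so most of these windows were not poor in SP1_PB insertions by count. Their SP1_PB counts were low relative to the many WT_PB insertions. The windows were picked by p from these same counts, so their ratios tend to overstate the difference. The leading window, chromosome 4 from 30.35 to 30.40 Mb, had 136 WT_PB insertions, 55, 37 and 44 per library, against 3 of SP1_PB, a ratio of 0.122 (0.0387 to 0.382, adjusted Fisher's exact p = 4.06e-05). The windows on the same chromosome at 30.45, 30.60 and 30.55 Mb had 86, 83 and 50 WT_PB insertions against 2, 2 and 0, and that at 102.25 Mb had 91 against 3. On chromosome 9 from 21.55 to 21.60 Mb 86 WT_PB insertions stood against 1, and on chromosome 8 from 128.30 to 128.35 Mb 95 against 3. The window on chromosome 12 at 74.30 Mb had 68 against 1, that on chromosome 8 at 86.85 Mb 64 against 1, and that on chromosome 1 at 84.40 Mb 58 against 0.

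These 10 calls depended on how insertions were counted and on the SP1_PB libraries used. Without SP1_PB replicate 1 none of the 10 was called and without SP1_PB replicate 2 only the window on chromosome 4 at 30.35 Mb was, and with 1 insertion per 1 kb cluster none was. Without positions in more than 1 library 6 of the 10 calls were lost. All 10 ratios stayed below 1: with 0.5 insertions added to each group they ran from 0.0471 to 0.211 with all libraries and positions, from 0.0734 to 0.332 without SP1_PB replicate 1, from 0.0755 to 0.292 without SP1_PB replicate 2, from 0.0563 to 0.245 without positions in more than 1 library, and from 0.0997 to 0.440 with 1 kb clusters.

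Whole chromosomes differed as well. Chromosome 19, dense in SP1 peaks, took 7.89% ± 0.431 of SP1_PB and 2.19% ± 0.0641 of WT_PB insertions, a ratio of 3.59. Chromosomes 22, 16, 17, 11, 20 and 1 also had higher SP1_PB shares, with ratios of 1.86, 1.60, 1.58, 1.18, 1.17 and 1.13. Chromosomes 2, 3, 4, 5, 6, 7, 8, 10, 13, 18 and Y had lower shares. Because shares sum to a whole, higher shares on some chromosomes by themselves lower those on others. The lowest ratio was 0.564 on chromosome 4, with 4.03% ± 0.170 against 7.12% ± 0.203, followed by 0.590 on Y, 0.657 on chromosome 13, 0.718 on chromosome 5 and 0.749 on chromosome 8. Ratios on the remaining 6 ran from 0.789 to 0.909. The share of Y was highest in WT_PB replicate 3, at 0.428% against 0.248% and 0.264% in the other WT_PB libraries, and without that library the ratio of Y was 0.713.

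Each of these 18 chromosomes passed Fisher's exact test after adjustment over 24 chromosomes, with adjusted p from below 1e-300 for chromosome 19 to 2.51e-04 for chromosome 7. The call of chromosome 7 was lost without SP1_PB replicate 2 (ratio 0.947), and that of chromosome 10 with positions within 3 bp merged, with 1 insertion per 1 kb cluster and without positions in more than 1 library. Across the 24 chromosomes the log2 ratio rose with the number of peaks per Mb (Pearson's r = 0.941, Spearman's rho = 0.929, permutation p = 0.0001 each, the smallest that 10000 permutations can give). Without chromosomes 19 and 17, the densest in peaks, r was 0.915. This relation was not among the planned tests and was the only one of its kind computed, and chromosomes are not independent replicates.

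**Figure D5:**
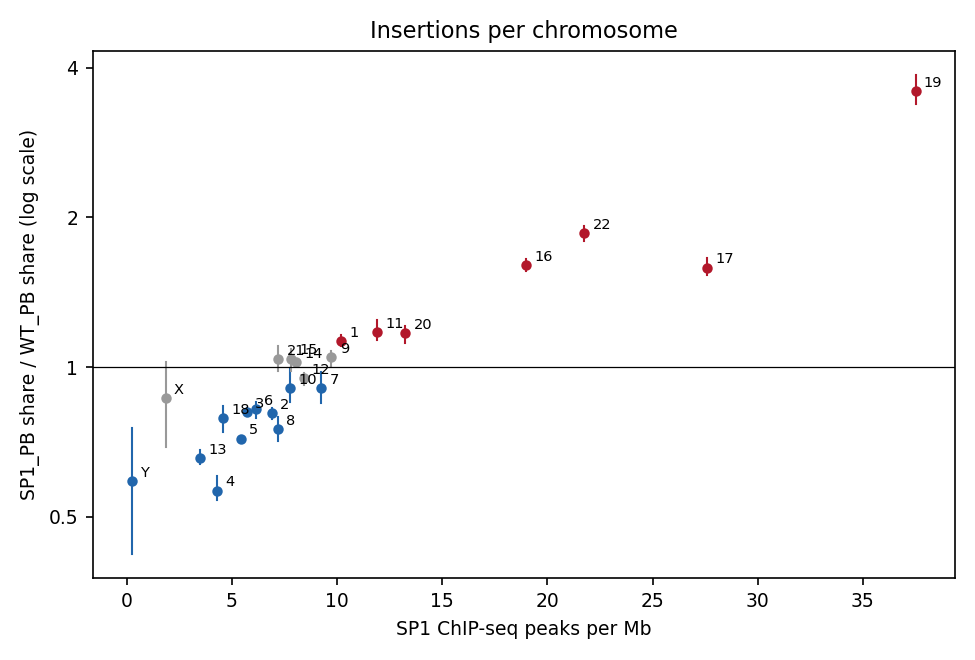
Points give the ratio of SP1_PB to WT_PB shares for 24 chromosomes on a log scale against SP1 ChIP-seq peaks per Mb, and vertical lines the range over the 6 pairs of libraries. Red marks the 7 chromosomes with higher and blue the 11 with lower SP1_PB shares; chromosome 19 has 37.5 peaks per Mb and a ratio of 3.59.

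Identical positions were found in every pair of libraries, and most often in the SP1_PB pair. The SP1_PB libraries shared 2913 positions, 20.1% of the smaller library, of which 66.7% lay within 1 kb of a peak. Pairs of WT_PB libraries shared 1710 to 2484 positions, 2.98% to 4.22% of the smaller, and pairs across groups 4.31% to 6.27%. The number that chance would give over TTAA sites was not computed.

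The 5 genes with the highest values in the same cell line included ribosomal and actin cytoskeleton genes. RPLP1 and RPL8, which encode ribosomal proteins, stood at 8979.84 and 3203.42 RPKM, TMSB10 and ACTG1 of the actin cytoskeleton at 3477.6 and 3099.51, and the cytokine MIF at 2664.92. Of 20423 genes, 11638 (57.0%) had at least 1 RPKM and 3398 (16.6%) were listed at 0. These are values of 1 library, and no test was possible.

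SP1 itself, at 47.96 RPKM and rank 1195 of all genes, was the highest of the 26 SP and KLF family members, which share its type of zinc fingers. KLF10 followed at 47.04, then KLF2 at 34.2, KLF4 at 27.5, KLF5 at 21.9 and SP2 at 18.6. KLF6, KLF16 and KLF13 lay at 15.1, 15.0 and 13.6, and KLF7, KLF3, SP3, SP6, KLF11 and KLF9 between 8.78 and 2.09. KLF15, KLF14 and SP4 lay at 1.80, 1.19 and 1.04. KLF12, KLF1, SP5, SP9, KLF8, SP8 and SP7 lay below 1 RPKM, and KLF17 was listed at 0. The family's median was 3.89 RPKM, above 84.5% of random lists of its size.

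Partners of SP1 were all at 1 RPKM or more, with a median of 10.6 over 16 genes, above 99.1% of random lists. HDAC1, a histone deacetylase, had 92.6 RPKM, and NFYC and NFYB, subunits of a CCAAT-binding factor, 28.4 and 1.40. Genes known from textbooks as SP1 targets had a median of 21.8 RPKM over 20 genes, above 100% of random lists. They ran from the thymidine kinase TK1 at 177, NCL at 176, MYC at 176 and ODC1 of polyamine synthesis at 164 down to TYMS, which was listed at 0. Cell cycle genes had a median of 21.2 RPKM over 34 genes, led by the replication helicase subunit MCM7 at 119, CCND1 at 109, CDK4 at 109 and CDC20 at 103, while RB1 was listed at 0. Housekeeping genes had a median of 242 RPKM, with GAPDH at 2306.73 and EEF2 at 1777.01, and YWHAZ, also of this list, was listed at 0. The medians of cell cycle and housekeeping genes were also above 100% of random lists. Colon epithelium markers were above 98.9%, Wnt targets above 94.8% and mismatch repair genes above 82.9%. A high place was thus not particular to lists related to SP1. Endothelial, leukocyte and fibroblast markers were above only 1.65%, 2.29% and 1.17%.

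Markers of colon epithelium had a median of 9.19 RPKM with genes listed at 0 and 20.6 without them, and 10 of the 19 listed reached 1 RPKM. The keratins KRT19, KRT8 and KRT18 stood at 543, 378 and 268.1 and the claudin CLDN7 at 198, while TFF3, a product of goblet cells, and LGALS4 were listed at 0. Of the members outside the naming rule, KRT20, MUC2, GPA33, VIL1, CEACAM5 and CDX1 lay between 0.238 and 0.0242 RPKM, and FABP1 was listed at 0. Wnt targets had a median of 6.93 RPKM, with CD44 at 66.7 and DKK1 at 53.7, and LGR5 and LEF1 were listed at 0. Mismatch repair genes had a median of 4.97 RPKM, from PCNA at 66.3 and POLD1 at 24.5 down to MLH3 at 0.892 and MSH3 at 0.461. The medians of endothelial, leukocyte and fibroblast markers were 0.0316, 0.0625 and 0.00781 RPKM with genes listed at 0 and 0.146, 0.168 and 0.125 without them. Only 1 member of each reached 1 RPKM: ENG at 1.72, CD68 at 8.65 and COL1A1 at 14.5.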

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

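Of the tests in this part, only that of positions with at least 10 reads was chosen before its result was seen. The files list some positions in several lines, a detail that no comparison above uses. Such positions made up 14.7% ± 3.90 of the SP1_PB libraries (17.4% and 11.9%), above the 3.97% ± 1.89 of the WT_PB libraries (4.09%, 5.80% and 2.02%). Deeper sequencing with errors in the bar code of the transposon would add lines with few reads. Among positions with at least 10 reads, however, those with at least 2 lines of 5 or more reads each were 7.20 times as frequent in SP1_PB as in WT_PB (13.5% ± 1.61 against 1.88% ± 0.312), and the ratio ran from 4.10 to 6.98 within 4 classes of read number, which argues against that explanation for the whole excess. Repeated insertion of the fusion at preferred positions near SP1 peaks is a candidate explanation: of such positions 69.5% and 70.1% lay within 1 kb of a peak in the SP1_PB libraries, against 41.9% and 42.2% of the other positions with at least 10 reads. The WT_PB libraries showed the same tendency (22.2% to 25.6% against 9.31% to 10.1%), and whether lines stand for separate bar codes, strands or digests stays open.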

How the results depend on the processing

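Alternatives with positions merged within 3 bp, each listed line counted, libraries reduced to the smallest, 1 kb clusters for windows, both SP1_PB libraries past an unadjusted p, removal of positions in more than 1 library for peak strength and chromosomes, and all those for the fold over random except the left-out libraries were chosen after seeing the data. The ratio of shares near a peak kept its direction at an exact p under 0.05 in all 22 alternatives with a test. The other of the 23 alternatives, weighted by reads, also kept the direction but had no test. The rule on single libraries was not applied again there. Over distances it ran from 2.83 within 10 kb to 11.3 inside peaks. At 1 kb from the edge of any peak it ran from 4.79 with at least 5 reads to 5.65 with each listed line counted. It was 5.10 with positions within 3 bp merged and, weighted by reads with no test, 4.86. The SP1_PB fold over random was 12.5 with at least 2 reads, 10.8 without positions in more than 1 library and 12.1 to 12.2 with 1 SP1_PB library left out; the WT_PB fold was 3.26 and 2.51 in the first 2 of these. Within each group of peaks by strength the SP1_PB excess kept its call in every alternative run, but these calls do not test the rise with score. The ratio in the highest over that in the lowest group was 1.22. In the alternatives by score it ran from 1.15 with the replicate block to 1.28 without positions in more than 1 library. The middle 2 groups did not rise in order with at least 2 reads, with the replicate block, without WT_PB replicate 3 or without SP1_PB replicate 1. Higher and lower windows numbered 1250 and 5 at 10 kb, 621 and 42 at 200 kb, 333 and 439 at 1 Mb, 764 and 14 with no minimum, 522 and 5 without positions in more than 1 library, 817 and 12 with both libraries required, 706 and 11 with positions within 3 bp merged, 1390 and 63 with each listed line counted, 228 and 0 with 1 insertion per 1 kb cluster, 424 and 17 with libraries reduced to the smallest, and 375 to 971 and 1 to 36 with 1 library left out (375 and 1 without SP1_PB replicate 1, 482 and 1 without SP1_PB replicate 2). The edgeR quasi-likelihood test called 758 and 29, of which 742 and 22 were also called above, and 1994 windows at an unadjusted p under 0.05. Window sizes change the number of windows tested, and fewer insertions lower what can be called; otherwise the cause was not tested. With a replicate block, without WT_PB replicate 3, 899 and 34 windows were called and the ratio near peaks was 5.23. The deviations of same-numbered libraries had a correlation of -0.0236 over 720 windows. With 2 libraries per group in that comparison the deviations mirror each other, so this is a single value. It cannot decide whether the numbers pair the libraries. Over these alternatives chromosome counts stayed at 7 to 8 higher and 10 to 13 lower; among insertions beyond 10 kb of peaks 8 were higher and 6 lower. Leaving out genes listed at 0 raised 9 of 11 list medians, that of colon epithelium markers to 20.6 and that of fibroblast markers from 0.00781 to 0.125. The balance of windows turned at 1 Mb, where lower outnumbered higher. Alternatives set beforehand for gene starts, gene bodies and expression classes were not run. Depth limits the windows: a window with any insertion held on average 3.70 WT_PB insertions, and the simulated test missed most changes.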

Other observations

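All values in the first 2 paragraphs, and the tests of distance for shared positions, were chosen after the data had been seen. Away from called peaks the groups still differed by the number of peaks around. Among insertions more than 10 kb from any peak, those with 21 or more peaks within 500 kb made up 19.6% ± 0.183 of SP1_PB (n = 2) and 9.45% ± 0.275 of WT_PB insertions (n = 3), a ratio of 2.08 (2.00 to 2.16, Fisher's exact p = 3.39e-252). Those with no peak within 500 kb made up 6.95% ± 0.199 and 14.7% ± 0.969, a ratio of 0.476 (0.447 to 0.507). Chromosome 19 took 3.03% ± 0.0829 of SP1_PB and 1.39% ± 0.0750 of WT_PB insertions beyond 10 kb of peaks, a ratio of 2.18. Chromosomes 6, 7, 10, 18 and Y lost their lower call there, with ratios of 0.979, 0.931, 1.01, 0.935 and 0.986, and chromosome 20 lost its higher call (1.09), while chromosomes 14 and 15 gained one (1.16 and 1.19). Chromosome X, poor in peaks and not called, went from 0.865 to above 1 (adjusted Fisher's exact p = 5.21e-06).

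Some regions took many insertions of the wild-type transposase. The 10 windows of 50 kb with the most WT_PB insertions, picked on that count, held 86 to 136, where a window with any insertion held 3.70 on average, and 9 of the 10 held no SP1 peak. SP1_PB insertions there numbered 1 to 8, also above their average of 0.671. Beside 5 lower windows named above and chromosome 4 from 30.40 to 30.45 Mb (116 WT_PB and 6 SP1_PB insertions), they lay on chromosome 10 from 114.25 to 114.30 Mb (127 WT_PB and 8 SP1_PB insertions), chromosome 3 from 113.10 to 113.15 Mb (113 and 8), chromosome 2 from 182.35 to 182.40 Mb (98 and 8) and chromosome 9 from 21.65 to 21.70 Mb (97 and 5). All 3 WT_PB libraries contributed to each. Insertions with more reads lay near peaks more often in every library, from 6.64% at 1 read to 10.4% above 100 reads in WT_PB replicate 1 and from 35.6% to 49.0% in SP1_PB replicate 1.

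The SP1_PB libraries shared 2913 identical positions, far more than any other pair relative to their size. Carry-over of reads between libraries would leave few reads in the receiving library, yet of shared positions with over 100 reads in one library 71.4% or more had over 10 reads in the other. A common pool of cells as the whole cause would share positions alike at all distances, but sharing inside peaks was 5.80 times that beyond 100 kb (32.4% against 5.59%). Inside peaks the rate of 99.9 identical positions per 1000 by 1000 positions compared was within the 99.8 to 103 of the WT_PB pairs, though pairs across groups had only 49.0 to 52.8, so more SP1_PB insertions in peaks are a candidate explanation for that part alone. Outside peaks the SP1_PB pair exceeded all others, with 46.1 at 1 to 10 kb against at most 6.53, and beyond 100 kb with 30.6 against 1.30 to 2.92 across groups and 0.776 to 1.29 for WT_PB pairs; there a common source of cells or DNA and preferred sites outside the called peaks cannot be told apart.

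Chromosome X took 3.14% of the insertions of WT_PB replicate 3 against 2.21% and 2.41% of the other WT_PB libraries, a ratio of 1.36 (1.28 to 1.44). Reads placed at a few repeats would raise few places, but the median ratio over 16 bins of 10 Mb was 1.38 and 15 of the bins were above 1. At positions with at least 5 reads the ratio was 1.02 (0.920 to 1.13), and at positions with 1 read 1.75 (1.60 to 1.91), so background positions with few reads are a candidate source of the excess. The groups give no biological explanation for a difference between replicates, and none was tested.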
